A study of Danio rerio with 9 samples.

How the data were processed

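The series holds 9 arrays of total RNA from whole zebrafish embryos, labelled with biotin and hybridised 1 sample per array, with 3 arrays for each of uninjected control, pitx2ab morpholino and tbx5 morpholino. The deposited table holds 1 log2 intensity per probe set and array, made by the authors, with values from 3.58 to 14.22. The R package oligo is named per the submitters' processing notes, and its version, the background correction, the normalization and the summarization are not given in the sources used here. The quartiles of the 9 columns were nearly equal, so the values were used as deposited, with no further normalization. No genome build was given for the probes, and no coordinates are reported.

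The table has 75212 probe sets. A probe table pairs 21661 of them with gene symbols, of which 20806 have 1 symbol and 855 several; the other 53551 are unnamed here. Symbols were checked through Entrez identifiers against a RefSeq gene table of assembly GRCz12tu, used for names only. Identifiers of 20323 probe sets were found there, and 1 symbol was updated. Probe sets with several symbols or none were left out of the gene tests. For 1365 genes with more than 1 probe set the one with the highest mean over the 9 arrays was kept, which left 19260 genes. Symbols are those of the array's annotation and can be old.

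Groups were taken from the sample labels. All 9 arrays entered 1 linear model per gene with a term per group and no replicate block, fitted with limma 3.58.1 (lmFit and eBayes, default prior) in R 4.3.3, with 6 residual degrees of freedom and a prior worth 6.51. The comparisons were tbx5 morpholino against control, pitx2ab morpholino against control and tbx5 against pitx2ab morpholino, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05 and no fold threshold. Gene lists for tissues, cell types and pathways, 36 in all, were fixed with 1208 symbols, of which 1078 matched a measured gene by symbol or synonym; 2 were left out because the only match was another gene's alias. Lists were tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, beside camera with an estimated correlation and fry. Tables were prepared with Python 3.11.15 and pandas 2.3.3 and figures drawn with matplotlib 3.10.9.

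Genes were named by rule: the target genes and, per comparison, the 10 highest and 10 lowest log2 changes among genes that passed, whose groups did not overlap and whose brighter group mean lay above 7.27, the median of all probe sets. The rule adds up to 4 members with the smallest p of each list that passed and up to 4 passing members of any other list. Symbols that are only clone or locus names were replaced by the next gene. The groups, tests, lists, naming rule and alternatives were set before the data were examined. Genes named outside the rule are given as such. Not every gene that the rule picked is shown, and those left out include members of lists that were not called.

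The gene test and the list test were tested on simulated data with 200 changed genes among 19260. For tbx5 against control, 85.1% of genes changed by 0.5 on the log2 scale were recovered and 100% of those changed by 1 or 2, with 5.9% of calls false. For pitx2ab against control the shares were 80.6%, 98.5% and 100%, with 3.6% false, and for tbx5 against pitx2ab 80.6%, 100% and 100%, with 3.6% false. A list shifted by 0.2 was called in each comparison and 0 of the others were. The noise was drawn independently for each gene, so false list calls from correlated genes were not tested. In the real arrays the estimated correlation was, for example, 0.12 in the lens list and 0.262 in the neuron and glia list. Each comparison was simulated once, with far fewer changed genes than the 8807 that passed for pitx2ab against control. The passing genes had a median absolute log2 change of 0.334 for tbx5 and 0.373 for pitx2ab against control. Both lie below the smallest change of 0.5 given to the 200 genes, so recovery of such changes was not measured. Shared controls were simulated 100 times with unchanged groups.

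Alternatives were each probe set on its own, averaged probe sets, genes above the median intensity only, cyclic loess, median centring, only the groups compared in the fit, the replicate number as a block, array weights, a trended and robust prior, and leaving out each array in turn. Array files, raw intensities and background signals were not used here, so no probe set was called absent. The depth of an array cannot be counted as reads can; the 3 arrays per group limit the precision.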

Results

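RNA from whole zebrafish embryos at 56 hours post fertilisation was measured on 9 one-colour arrays. There were 3 samples of uninjected wild-type controls, 3 of embryos injected with a pitx2ab morpholino and 3 of embryos injected with a tbx5 morpholino. A morpholino is a synthetic antisense oligonucleotide that blocks the translation or the splicing of the RNA it pairs with. Tbx5 is a T-box transcription factor needed for heart and pectoral fin development, and Pitx2 is a homeobox transcription factor with roles in left-right asymmetry, the eye and the jaw. The labels describe separate experiments on siblings, and the p-values of single genes measure the spread between these 9 samples. Camera's p-values for gene lists at the preset correlation compare a list's genes with the other genes. There the correlation between genes was fixed and not estimated from these samples. The controls were uninjected, so each comparison with them holds the injection as well as the morpholino.

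The values were log2 intensities, with array medians between 7.24 and 7.31, and 19260 genes were tested. The number of arrays limits the precision. A rank test of 3 against 3 samples could not go below an exact two-sided p of 0.1. Adjusted p-values of single genes and probe sets below come from limma's moderated test, and those of gene lists from camera. The first principal component held 73.5% of the variance and placed the pitx2ab arrays at 32.9 to 36.3 and all others at -18.98 to -15.98. The second held 10.3% and placed the controls at 7.38 to 14.3 and the tbx5 arrays at -13.9 to -4.81.

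The genes named in the labels were examined first. The sample labels say tbx5 and the series design says tbx5a, and no oligonucleotide sequence is given, so which of the paralogs it pairs with is not settled here. In the tbx5 morpholino embryos tbx5a rose by 0.74 on the log2 scale (1.67-fold), from 9.50 ± 0.07 in controls to 10.24 ± 0.12 (SD, n = 3; adjusted p = 0.000171). The paralog tbx5b fell by 0.45, from 9.42 ± 0.03 to 8.97 ± 0.14 (adjusted p = 0.00489). In the pitx2ab morpholino embryos tbx5b rose by 0.50 to 9.92 ± 0.01 (adjusted p = 7.35e-05). There tbx5a stood at 9.53 ± 0.01, a log2 difference of 0.03 (adjusted p = 0.731) that was -0.009 without control replicate 2. A morpholino that blocks translation need not lower the RNA it pairs with, and the labels do not give the type used, so these levels do not check the labels. No probe set used here was named pitx2, and that gene was not analysed.

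The comparison of tbx5 morpholino with uninjected embryos asked which RNAs differ after injection of this morpholino. In the lens list 18 of 47 measured genes fell, 0 rose and 29 did not pass (camera adjusted p = 4.47e-08, adjusted p = 0.406 with an estimated correlation). The largest fall was in col10a1a, which encodes the type X collagen of hypertrophic cartilage and forming bone, at 7.22 ± 0.34 against 10.15 ± 0.17 in controls (7.63-fold lower; log2 change -2.93; adjusted p = 1.66e-06). The largest rise was in gnmt, glycine N-methyltransferase, at 10.81 ± 0.12 against 8.70 ± 0.09 (4.3-fold higher; adjusted p = 1.23e-08). Each of these groups held 3 samples, and the 3 values of 1 group lay beyond the 3 of the other.

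Among the other strongest rises, fhad1 changed by 1.74 on the log2 scale (3.34-fold), although its second probe set differed by -0.07. The immediate early transcription factor genes fosab and fosl1a rose by 1.28 and 1.12. The ultraviolet cone opsin gene opn1sw1 rose by 1.25 (2.38-fold, adjusted p = 0.00299). The cholesteryl ester transfer protein gene cetp rose by 1.19, and sdhdb, itm2ba, cyp4v2a and sat2b rose by 0.84, 0.81, 0.79 and 0.78. Lower genes included ifitm5, known from bone-forming cells (-1.58; 2.99-fold lower; adjusted p = 1.52e-07), and entpd5a, a gene of bone mineralisation (-1.35; adjusted p = 0.000552). For col10a1a a second probe set gave -2.19 and the dimmest one -0.11. The gene paqr3b was at -1.54 in the probe set used (adjusted p = 0.00427) and at -0.04 in its other one. Lens transcripts made up the rest of the lowest 10, among them crybb1 (-1.51), cryaa (-1.48), cryba1b (-1.43) and the lens aquaporin gene mipb (-1.34), together with capn3a (-1.30) and lctlb (-1.25). For cryaa the adjusted p of 0.0112 became 0.06 without control replicate 1 and 0.0505 without tbx5 replicate 3. With each probe set tested on its own the adjusted p was 0.0748 for cryaa, 0.0741 for fosl1a, 0.0597 for sdhdb and 0.0507 for cryba1b.

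In all, 1044 genes passed the threshold in tbx5 morpholino embryos, 415 higher and 629 lower (576 and 627 after cyclic loess), and 24 of them changed by more than 2-fold. The values of the groups did not overlap for 24.9% of genes, against 10% by chance. The count of 1044 depended on single arrays. It was 205 without control replicate 1, 275 without control replicate 3, 505 without tbx5 replicate 2 and 299 without tbx5 replicate 3. Without tbx5 replicate 1 it rose to 1542, and without pitx2ab replicate 3 it was 693. The pitx2ab arrays enter this comparison only through the shared estimate of the spread. Of 64 genes named in this comparison that passed, 27 lost their calls without control replicate 1, 23 without control replicate 3, 20 without tbx5 replicate 3 and 32 with each probe set tested on its own. The count was 466 (233 higher and 233 lower) with each probe set tested on its own, 578 with only these groups in the fit and 1685 with array weights.

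**Figure D1:**
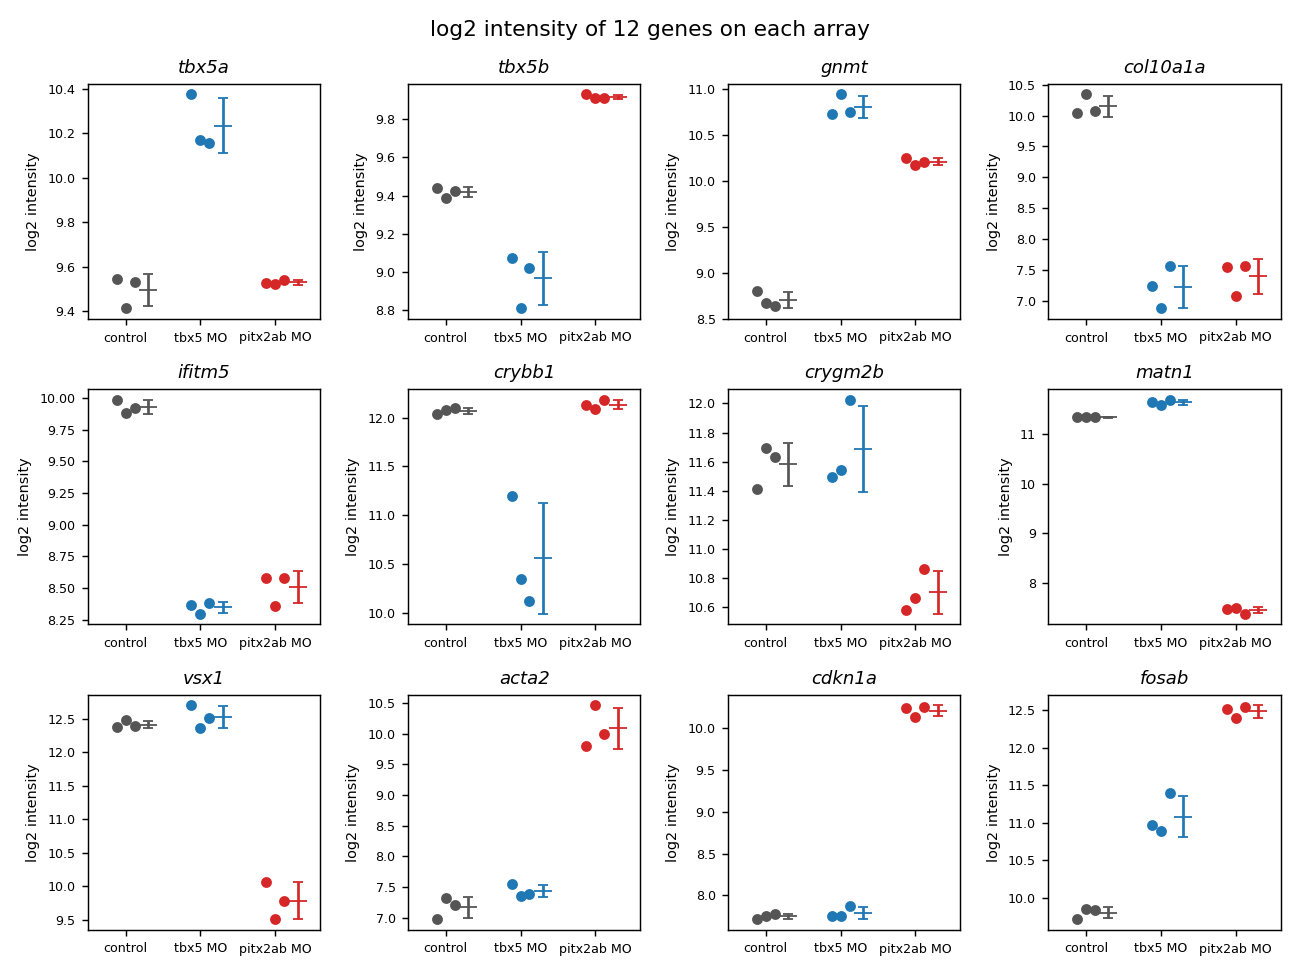
Log2 intensity (vertical axes) of 12 genes on each of the 9 arrays, grouped as uninjected control, tbx5 morpholino (MO) and pitx2ab morpholino; points are single arrays and the bar beside them is the mean with the SD of 3. The col10a1a values lay near 10.15 in controls and at means of 7.22 and 7.39 under the tbx5 and pitx2ab morpholinos, while matn1 was low only in the pitx2ab arrays (7.44 ± 0.06).

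Of 36 gene lists fixed beforehand, 11 passed camera's competitive test in tbx5 morpholino embryos, 4 toward higher and 7 toward lower values. In the lens list 18 genes fell and 29 did not pass, and adjusted over the list alone 23 fell and 1 rose (median log2 change -0.18, camera adjusted p = 4.47e-08; adjusted p = 0.406 with an estimated correlation). Without control replicate 1, 11 lens genes fell. The members with the smallest p were gje1a (-0.57), mipb, crybb1l2 (-0.88) and crybb1. The gamma M2 crystallin genes crygm2b, crygm2c, crygm2d1 and crygm2d13, singled out after their values were seen, did not pass, with log2 differences of 0.11, -0.05, -0.18 and -0.27. The sign turned for crygm2b without tbx5 replicate 3 (-0.062) and for crygm2c without tbx5 replicate 1 (0.038), and crygm2d13 passed without tbx5 replicate 3 (adjusted p = 0.0435).

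Photoreceptor genes went the other way in tbx5 morpholino embryos. Among 41 measured, 5 rose, 0 fell and 36 did not pass, and adjusted over the list alone 12 rose and 1 fell (median 0.10, camera adjusted p = 3.14e-05; adjusted p = 0.406 with an estimated correlation). The risen members were opn1sw1, the recoverin gene rcvrna (0.49), the cone phosphodiesterase gene pde6ha (0.41), gngt2b (0.37) and, named after its values were seen, rom1b (0.41, but -0.006 in its dimmer probe set, and adjusted p = 0.143 with both averaged). Pigment cell genes also rose, 6 of 27 with 0 lower and 21 not passing, and 7 adjusted over the list alone (camera adjusted p = 0.000702; adjusted p = 0.146 with an estimated correlation). They included the endothelin receptor gene ednrba (0.52; adjusted p = 0.00106), pnp4a (0.38), the melanocortin receptor gene mc1r (0.35) and slc45a2 (0.35). The stress and immediate early list had 7 of 37 genes higher, 0 lower and 30 not passing, and 13 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.003; adjusted p = 0.406 with an estimated correlation). Besides fosab and fosl1a, junba rose by 0.71 and txnipa by 0.35. In the myeloid and inflammation list 4 of 29 rose, 0 fell and 25 did not pass, with 5 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0191; adjusted p = 0.406 with an estimated correlation). These were the prostaglandin synthase genes ptgs2b (0.59) and ptgs2a (0.32), cebpb (0.49) and socs3a (0.75). The myeloid list was not called without tbx5 replicate 2 (0.0585), without tbx5 replicate 3 (0.0541) or after cyclic loess (0.0561). The number of risen genes fell to 3 for photoreceptor without any 1 control, to 1 for pigment cells without control replicate 1, 2 without control replicate 3 and 3 without tbx5 replicate 3, to 4 for stress and immediate early without control replicate 1, control replicate 3 or tbx5 replicate 3, and to 2 for myeloid and inflammation without control replicate 3. Single arrays ended some gene calls too, with the highest adjusted p at 0.168 for rom1b, 0.0711 for gngt2b, 0.0569 for pnp4a, 0.0658 for mc1r, 0.0901 for slc45a2, 0.0658 for ptgs2a and 0.0842 for socs3a; control replicate 1 or 3 was among the arrays for each. With only these groups in the fit rom1b and gngt2b did not pass (0.0855 and 0.0577).

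The pectoral fin and limb list, which covers the fin that tbx5 is known for, moved toward lower values in tbx5 morpholino embryos. It had 5 of 43 genes lower, 0 higher and 38 not passing, and 10 lower adjusted over the list alone (median -0.06, camera adjusted p = 0.0119; adjusted p = 0.56 with an estimated correlation). The posterior Hox gene hoxa13b fell by 0.64 (adjusted p = 0.00105), and sall1a (-0.33), sp9 (-0.34), dlx2a (-0.40) and, named after its values were seen, sp8b (-0.40) fell less. The fin bud gene fgf10a, also named after its values were seen, differed by -0.06 (adjusted p = 0.582). In the list of cardiac transcription factors and valve genes 4 of 29 fell, 0 rose and 25 did not pass, and 6 fell adjusted over the list alone (camera adjusted p = 0.0119; adjusted p = 0.406 with an estimated correlation). They were foxn4 (-0.97; adjusted p = 0.00122; -0.37 in its second probe set), irx1b (-0.51), irx1a (-0.44) and the Notch receptor gene notch1b (-0.32). Only 1 gene of the fin list fell without control replicate 1, control replicate 3, tbx5 replicate 2 or tbx5 replicate 3, 8 fell without tbx5 replicate 1, and of the cardiac list 1 fell without control replicate 1, control replicate 3 or tbx5 replicate 3 and 2 without tbx5 replicate 1. The fin list was not called without control replicate 1 (0.065) or tbx5 replicate 2 (0.0572). Leaving out control replicate 1, control replicate 3 or tbx5 replicate 3 ended the calls of irx1b, irx1a, notch1b, sall1a, sp9, dlx2a and sp8b, whose highest adjusted p-values were 0.0631, 0.123, 0.169, 0.0901, 0.107, 0.112 and 0.189. With only these groups in the fit irx1a, notch1b and dlx2a did not pass either (0.0526, 0.0826 and 0.0656), nor did notch1b after cyclic loess (0.0551). The cardiac sarcomere list was not called, with 1 of 24 genes higher and 1 lower (median 0.055, camera adjusted p = 0.122). It passed without tbx5 replicate 1 (0.0347). Cardiac calcium handling and ion channel genes were not called either, with 0 of 29 higher and 2 lower (camera adjusted p = 0.783). As the RNA came from whole embryos, the tissue in which these genes changed is not shown.

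Cartilage and craniofacial genes included col10a1a and entpd5a, already given, and fgfbp2b (-0.41) and sox9b (-0.38, named after its values were seen) among 4 lower members of 42 in tbx5 morpholino embryos. The matrix gene matn1 was the 1 higher member (0.30), 37 did not pass, and 1 rose and 5 fell adjusted over the list alone (camera adjusted p = 0.0119; adjusted p = 0.406 with an estimated correlation). In the fast skeletal muscle list 4 of 37 fell, 0 rose and 33 did not pass, also 4 adjusted over the list alone (camera adjusted p = 0.0241; adjusted p = 0.406 with an estimated correlation). They were the calcium channel gene cacna1sa (-0.43; adjusted p = 0.00413), pvalb3 (-0.31), atp2a1l (-0.29) and the ryanodine receptor gene ryr1b (-0.26). Neuron and glia genes had 5 of 38 lower, 0 higher and 33 not passing, with 1 higher and 10 lower adjusted over the list alone (camera adjusted p = 0.00663; adjusted p = 0.57 with an estimated correlation). Those were the synaptophysin gene sypa (-0.45), stmn2b (-0.58), tuba1c (-0.84), neurog1 (-0.38) and, named after its values were seen, cnp (-0.29). In the cell cycle list the replication helicase gene mcm4 (-0.30) was the 1 member of 37 to fall, 0 rose and 36 did not pass, and the count was the same adjusted over the list alone (camera adjusted p = 0.00436; adjusted p = 0.406 with an estimated correlation). Without control replicate 1 the lower genes numbered 2 for cartilage, 1 for muscle and 2 for neuron and glia, without control replicate 3 or tbx5 replicate 3 they numbered 1 for muscle, and without tbx5 replicate 1 they numbered 7 for cartilage, 10 for neuron and glia and 5 for cell cycle. They were 2 for muscle without pitx2ab replicate 3 and 3 for neuron and glia without tbx5 replicate 2 or 3. The muscle list was not called without control replicate 2 (0.065), control replicate 3 (0.076) or tbx5 replicate 1 (0.187), or after cyclic loess (0.0561), and the neuron list not without tbx5 replicate 2 (0.128). Calls that ended without control replicate 1, control replicate 3 or further arrays were those of fgfbp2b, sox9b, matn1, pvalb3, atp2a1l, ryr1b, tuba1c, neurog1, cnp and mcm4, with highest adjusted p-values of 0.0684, 0.0836, 0.0645, 0.125, 0.121, 0.163, 0.0684, 0.1, 0.166 and 0.0901. The gene ryr1b also missed the threshold with averaged probe sets (0.0574), and ryr1b and cnp did after cyclic loess (0.0633 and 0.0552). So did ryr1b, pvalb3, atp2a1l and cnp with only these groups in the fit (0.0823, 0.0592, 0.0549 and 0.082).

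The comparison of pitx2ab morpholino with uninjected embryos showed many more changed genes. The cartilage matrix gene matn1 fell from 11.35 ± 0.01 to 7.44 ± 0.06 (SD, n = 3), 15-fold lower (adjusted p = 3.77e-13). The gene vsx1, a homeobox gene known from bipolar cells of the retina, also fell, to 9.79 ± 0.27 against 12.41 ± 0.06 (6.17-fold lower). The smooth muscle actin gene acta2 rose from 7.16 ± 0.17 to 10.09 ± 0.34 (7.6-fold; adjusted p = 1.17e-08). The cell cycle inhibitor gene cdkn1a, a target of p53, rose from 7.75 ± 0.03 to 10.21 ± 0.06 (5.52-fold; adjusted p = 7.99e-11).

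Other large rises in pitx2ab morpholino embryos were in the muscle ankyrin repeat gene ankrd1a (log2 change 2.91) and the sarcomere gene tcap (2.6). The immediate early genes fosl1a, fosab and junba rose by 2.84, 2.68 and 2.43. The leptin gene lepa rose by 2.6, ghrh, which encodes growth hormone releasing hormone, by 2.59 and the Polycomb gene cbx7a by 2.43. Genes that fell most after matn1 were prdm8a (-3.42; 10.7-fold lower) and col10a1a (-2.76; 6.78-fold lower), with col10a1a at -2.01 and -0.07 in its other probe sets. Next came vsx1 (-2.63), a2m2h (-2.56) and the retinal matrix gene egflam (-2.47). The phototransduction gene gnb3a (-2.45), samd7 (-2.42), the photoreceptor transcription factor gene crx (-2.36) and six7 (-2.36) completed the lowest 10. Genes prominent in the tbx5 comparison and looked up here after their values were seen were gnmt (1.51; adjusted p = 1.21e-08), fhad1 (2.36, but 0.28 in its second probe set, adjusted p = 1.11e-08) and ifitm5 (-1.42; adjusted p = 1.58e-08).

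In all, 8807 genes passed in pitx2ab morpholino embryos, 4360 higher and 4447 lower, and 408 changed by more than 2-fold. The balance turned with median centring, to 5078 higher and 4030 lower. The groups did not overlap for 57% of genes, against 10% by chance. With each of 75212 probe sets tested on its own, 15545 passed.

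Of the 36 lists, 9 passed in pitx2ab morpholino embryos, 6 toward higher and 3 toward lower values. A mixed split of these arrays also called 9 lists. Cardiac sarcomere genes rose almost as a whole, 21 of 24 higher, 0 lower and 3 not passing, with the same counts adjusted over the list alone (median 0.44, camera adjusted p = 1.13e-08; adjusted p = 0.0588 with an estimated correlation). Besides ankrd1a and tcap, xirp1 rose by 1.86 and popdc1 by 0.76. The RNA came from whole embryos, so these values do not show in which tissue the genes rose. The stress and immediate early list had 26 of 37 genes higher, 3 lower and 8 not passing, and 27 higher and 3 lower adjusted over the list alone (median 0.52, camera adjusted p = 1.46e-08; adjusted p = 0.202 with an estimated correlation). Its leading members were fosab, junba, fosl2 (1.59) and the small heat shock gene hspb9 (2.41, but 0.21 in a second, dimmer probe set). In the p53 response list 17 of 27 rose, 2 fell and 8 did not pass, with the same counts adjusted over the list alone (median 0.39, camera adjusted p = 4.95e-05; adjusted p = 0.0588 with an estimated correlation). Alongside cdkn1a, casp8 rose by 1.28, the p53 regulator gene mdm2 by 1.26 and gadd45ba by 1.27. The members that fell, named after their values were seen, were hspa5 (-0.53), egr3 (-0.23) and hspb11 (-0.24) in the stress list and tp53inp1 (-0.36) and ZMAT3 (-0.24) in the p53 list. Dimmer probe sets gave 0.072 for tp53inp1 and 0.008 for egr3, and with the probe sets of a gene averaged neither passed (adjusted p = 0.0574 and 0.232). Without control replicate 1 or pitx2ab replicate 2, egr3 and hspb11 no longer passed, with adjusted p up to 0.111 and 0.136 (0.0514 for hspb11 after cyclic loess and 0.0574 after median centring), and ZMAT3 did not pass without control replicate 2 or pitx2ab replicate 1 (up to 0.0744).

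Myeloid and inflammation genes had 11 of 29 members higher, 2 lower and 16 not passing in pitx2ab morpholino embryos, the same adjusted over the list alone (median 0.17, camera adjusted p = 0.0032; adjusted p = 0.268 with an estimated correlation). The matrix protease gene mmp9 rose by 1.97, socs3b by 1.73, socs3a by 2.32 and cebpb by 0.97. The macrophage gene mpeg1.1 (-0.83) and the lysozyme gene lyz (-0.40, but -0.013 in its dimmer probe set), named after their values were seen, fell. Interferon response genes had 8 of 31 higher, 1 lower and 22 not passing, and 7 higher and 1 lower adjusted over the list alone (median 0.11, camera adjusted p = 0.0253; adjusted p = 0.63 with an estimated correlation). The interferon regulatory factor genes irf1b, irf7 and irf9 rose by 1.37, 1.14 and 0.96 and isg15 by 0.87, and adar (-0.29, named after its values were seen) fell. The proteasome and ribosome biogenesis list had 24 of 39 higher, 9 lower and 6 not passing, and 25 higher and 9 lower adjusted over the list alone (camera adjusted p = 0.00055; adjusted p = 0.352 with an estimated correlation). Divided by name after its values were seen, its 25 ribosome biogenesis genes had 24 higher and 0 lower (median 0.72), and its 14 proteasome subunits had 0 higher and 9 lower (median -0.31). The nucleolar genes mybbp1a, rcl1, nle1 and nop58 rose by 0.98, 0.92, 0.90 and 0.86. The interferon list was not called without pitx2ab replicate 2 (0.0913) or after cyclic loess (0.2). The call of lyz ended without control replicate 1, control replicate 2 or pitx2ab replicate 3, with adjusted p up to 0.0811.

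Neuron and glia genes fell in pitx2ab morpholino embryos, 27 of 38 lower, 1 higher and 10 not passing, with the same counts adjusted over the list alone (median -0.51, camera adjusted p = 1.13e-08; adjusted p = 0.352 with an estimated correlation). The stathmin gene stmn1b fell by 1.44, the radial glia gene fabp7a by 1.23, the GABA synthesis gene gad2 by 1.15 and the synaptotagmin gene syt1a by 0.92. The proneural gene neurog1 rose (0.47; named after its values were seen). Cartilage and craniofacial genes had 18 of 42 lower, 4 higher and 20 not passing, the same adjusted over the list alone (median -0.11, camera adjusted p = 0.00225; adjusted p = 0.202 with an estimated correlation). With matn1 and col10a1a, entpd5a (-1.81) and fgfbp2b (-1.69) fell, and the higher members, named after their values were seen, were sox9b (0.53), chad (0.38), matn3b (0.31) and col9a1b (0.23). In the lens list 16 of 47 fell, 2 rose and 29 did not pass, and 15 fell and 2 rose adjusted over the list alone (median -0.18, camera adjusted p = 0.0269; adjusted p = 0.63 with an estimated correlation). Here the gamma M2 crystallins crygm2d13 (-1.13), crygm2c (-0.92) and crygm2b (-0.88) fell, as did crygm2d1 (-0.61), named after its values were seen. The dimmer crygm2d7, picked by the rule, stood at 5.65 to 5.84 against 6.23 to 6.51 in controls. The mean of 4 bright gamma M2 genes was 9.06 ± 0.10 against 9.94 ± 0.08 in controls (SD of 3 arrays). That of 22 other bright lens genes was 9.98 ± 0.02 against 10.23 ± 0.03, so those were lower too, by less. Single genes varied, with crybb1 differing by 0.06 (adjusted p = 0.816) and mipb by -0.18 (adjusted p = 0.406). The gene cryaa stood at 9.414 to 9.475 against 9.946 to 10.109 in controls. These classes and genes were looked up after their values were seen. The higher lens genes, likewise, were gja8b (0.40) and cryaba (0.21). The photoreceptor list had 13 of 41 lower, 3 higher and 25 not passing and was not called (median -0.05, camera adjusted p = 0.0862), although crx, pde6gb (-2.16) and rcvrna (-1.83) fell. The cone transducin gene gnat2 rose by 1.36, and guca1c (0.30) and grk1b (0.20), both named after their values were seen, rose less. That list was called without pitx2ab replicate 2 (0.0239) and after cyclic loess (0.0114). Single arrays, control replicate 2 or 3 among them, ended the calls of matn3b (0.0691), col9a1b (0.169), cryaba (0.0541) and grk1b (0.137, and 0.172 after cyclic loess), each with its highest adjusted p.

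**Figure D2:**
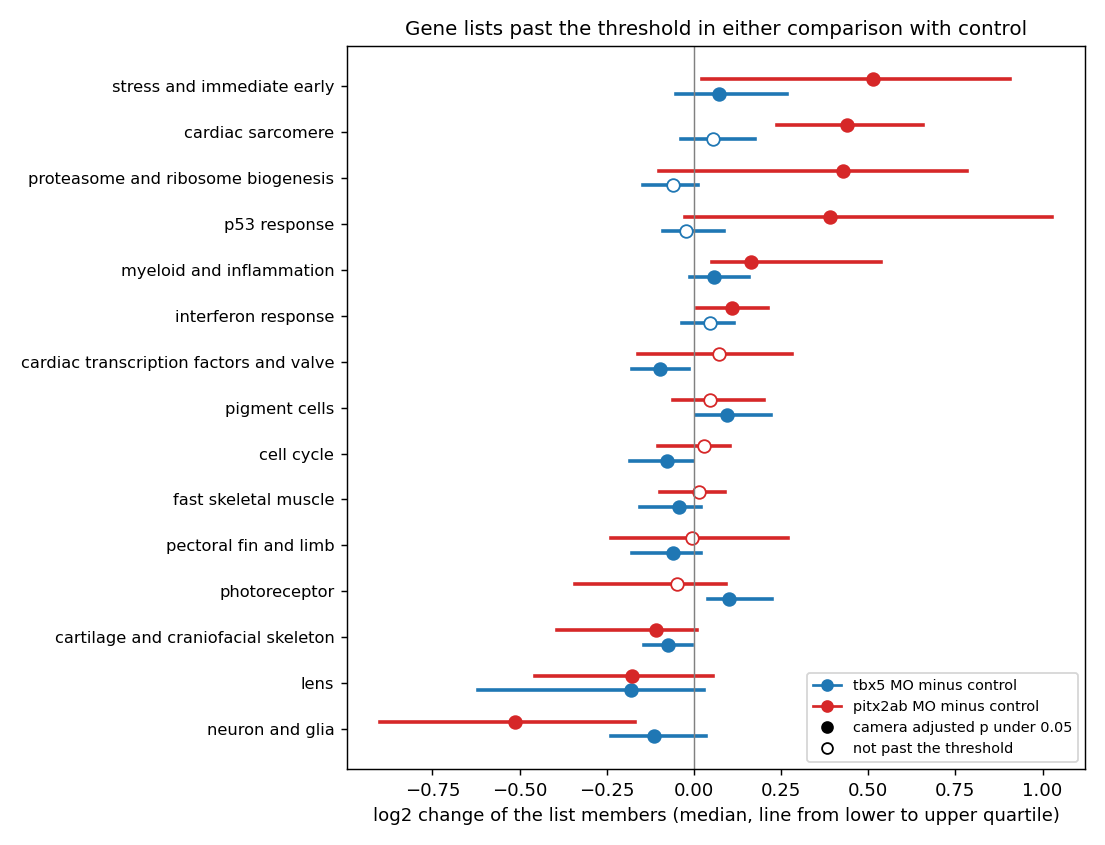
Median log2 change (horizontal axis; lines run from the lower to the upper quartile of the members) of each gene list past the threshold in either comparison with control, blue for the tbx5 and red for the pitx2ab morpholino; filled points passed camera at an adjusted p under 0.05. Neuron and glia genes sat at a median of -0.51 and stress genes at 0.52 in the pitx2ab comparison, against -0.12 and 0.07 in the tbx5 comparison.

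The direct comparison of the tbx5 with the pitx2ab morpholino, which the series design names, tests the difference between both effects. The gene matn1 was 18.5-fold higher in tbx5 than in pitx2ab morpholino embryos, at 11.65 ± 0.05 against 7.44 ± 0.06 (SD, n = 3; adjusted p = 1.49e-13). The hormone gene ghrh was 8.6-fold lower, at 5.56 ± 0.20 against 8.67 ± 0.08 (adjusted p = 4.05e-10). The gene tbx5a was higher by 0.71 and tbx5b lower by a log2 change of -0.95 (adjusted p = 3.81e-06 and 3.39e-07).

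After matn1, the genes most in favour of tbx5 morpholino embryos were prdm8a (log2 change 3.53), gnb3a (3.06), vsx1 (2.74), a2m2h (2.61), stxbp1b (2.44), cnrip1b (2.37) and the photoreceptor membrane gene prom1b (2.35). The genes rcvrn2 (2.37) and pcdh8 (2.35) were among them in the probe set used, with -0.02 and 0.003 in a dimmer one. In the other direction, after ghrh, were ankrd1a (-2.71), acta2 (-2.66), lepa (-2.58), cdkn1a (-2.43), cbx7a (-2.37), tcap (-2.34), hspb9 (-2.18; -0.23 in its dimmer probe set), bmb (-2.17) and the matricellular gene ccn1l1 (-2.05). In all, 9189 genes differed between the morpholinos, 4466 higher and 4723 lower in tbx5 morpholino embryos (4693 and 4688 after cyclic loess, 4134 and 5299 with median centring), with 485 over 2-fold. The groups did not overlap for 54.5% of genes, against 10% by chance, and 19218 of 75212 probe sets passed when each was tested on its own, 10672 higher and 8546 lower.

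Of the 36 lists, 6 passed between the morpholinos. Among the 10 splits of these 6 arrays into 3 and 3, 4 called at least as many lists, the real one included. Cardiac sarcomere genes were lower in tbx5 morpholino embryos for 17 of 24 members, higher for 0 and not passing for 7, with 19 lower adjusted over the list alone (median -0.41, camera adjusted p = 1.74e-06; adjusted p = 0.114 with an estimated correlation). Examples beyond ankrd1a and tcap were xirp1 (-1.89) and smyd1b (-1.07). Against uninjected embryos, 21 of these 24 genes were higher under the pitx2ab morpholino (median 0.44). Under the tbx5 morpholino 1 was higher and 1 lower than in uninjected embryos (median 0.055, camera adjusted p = 0.122). The stress list had 24 of 37 lower, 2 higher and 11 not passing, and 25 lower and 3 higher adjusted over the list alone (median -0.40, camera adjusted p = 3.08e-06; adjusted p = 0.374 with an estimated correlation), with junba at -1.72, fosl2 at -1.39 and atf3 at -1.37. In the p53 list 17 of 27 were lower, 2 higher and 8 not passing, and 17 lower and 3 higher adjusted over the list alone (median -0.39, camera adjusted p = 6.9e-05; adjusted p = 0.091 with an estimated correlation). There rps27l was at -1.91 (-0.999 in its dimmer probe set), casp8 at -1.36 and mdm2 at -1.31. The proteasome and ribosome biogenesis list had 26 of 39 lower, 8 higher and 5 not passing, the same adjusted over the list alone (median -0.48, camera adjusted p = 6.8e-05; adjusted p = 0.374 with an estimated correlation). All 25 ribosome biogenesis genes were lower, among them mybbp1a (-1.12) and bop1 (-1.11), and 8 proteasome subunits were higher and 1 lower; after cyclic loess 24 of the 25 were lower. Neuron and glia genes were higher for 25 of 38 members, lower for 3 and not passing for 10, with 25 higher and 4 lower adjusted over the list alone (median 0.32, camera adjusted p = 9.21e-06; adjusted p = 0.42 with an estimated correlation), led by stmn1b (1.43), gad2 (1.21) and fabp7a (1.18). Photoreceptor genes were higher for 21 of 41, lower for 1 and not passing for 19, with the same counts adjusted over the list alone (median 0.27, camera adjusted p = 0.000255; adjusted p = 0.42 with an estimated correlation). There rcvrna was at 2.32 and pde6gb at 1.96. Members against their list, named after their values were seen, were hsp90aa1.2 (0.39) and hspa5 (0.26), tp53inp1 (0.20) and ZMAT3 (0.34), neurog1 (-0.85), nefmb (-0.49) and inaa (-0.19), and gnat2 (-1.20). Of these, hspa5 (highest adjusted p 0.121), tp53inp1 (0.115) and inaa (0.187) lost their calls without pitx2ab replicate 3 or other single arrays. The call of tp53inp1 also ended with averaged probe sets (0.632; -0.127 in the dimmer one), that of hspa5 with only these groups in the fit (0.0614) and that of inaa there (0.0802), after cyclic loess (0.07), with array weights (0.0592) and with a trended and robust prior (0.0604).

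With an estimated inter-gene correlation camera called 0 lists in each of the 3 comparisons, with lowest adjusted p-values of 0.146 for tbx5 against control, 0.0588 for pitx2ab against control and 0.091 for tbx5 against pitx2ab. The directional fry test, which asks whether a list's genes move on balance one way, called 10, 19 and 26 of the 36 lists, and its mixed test 34, 36 and 36. The median, the mean and the camera direction had the same sign in every list named above.

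The overlap of both comparisons with uninjected embryos was examined last. Genes that changed the same way under both morpholinos numbered 440, with 183 higher and 257 lower, where independent lists would share 93.9 and 145.2. They included gnmt and fhad1, higher under both, and col10a1a and ifitm5, lower under both. Another 287 genes changed in opposite directions, where independent lists would give 238.2, and 317 changed under the tbx5 morpholino but did not pass under the pitx2ab one. Both comparisons used the same 3 controls, and simulations of unchanged groups against shared controls gave a median of 0 and a highest count of 1100 shared genes when the noise was correlated between genes, and 0 in all 100 simulations when it was independent. The controls were too few to split into separate sets of 2 or more. The highest count of 1100 with correlated noise lay above the observed 440, so part or all of the excess may come from sharing the controls. The shared count was 103 without control replicate 1, 131 without control replicate 3, 280 without pitx2ab replicate 3, 218 without tbx5 replicate 2 and 125 without tbx5 replicate 3, and it was 180 with each probe set tested on its own and 702 with array weights.

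Across the 19260 genes, which are not independent replicates, the log2 changes of gnmt, col10a1a and all others under both morpholinos had a Pearson correlation of 0.137. Unchanged groups simulated against shared controls gave a median of 0.51, with a range of -0.603 to 0.991. The covariance was 0.00814 and lay within the simulated range of -0.00392 to 0.0252 (median 0.0033, a difference of 0.00483, or 0.00448 with independent noise). The changes had the same sign for 55.1% of genes, also within the simulated range of 28.4% to 95% (median 67.1%). In these simulations no gene changed, whereas 8807 genes passed under the pitx2ab morpholino. The observed log2 changes had a variance of 0.143 under the pitx2ab and 0.0247 under the tbx5 morpholino. The simulated values thus cannot show whether both effects agree more or less than unrelated effects would. The correlation was 0.179 without control replicate 2 and 0.104 without tbx5 replicate 2.

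**Figure D3:**
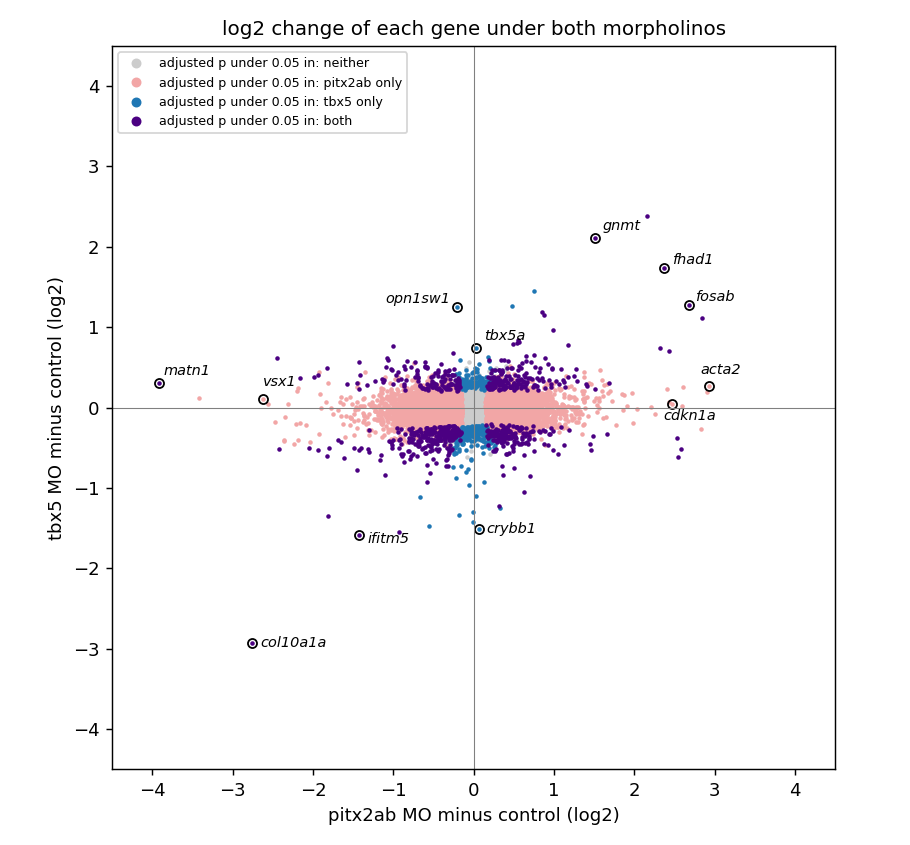
Log2 change of each gene under the pitx2ab (horizontal axis) and tbx5 (vertical axis) morpholino against uninjected controls, 1 point per gene, coloured by the comparisons in which its adjusted p was under 0.05; the named genes are circled. The genes gnmt (2.104 under tbx5 and 1.51 under pitx2ab) and col10a1a (-2.93 and -2.76) changed alike, and matn1 (0.30 and -3.91) did not.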

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

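The comparison of the real grouping with other splits of the arrays was planned before any result was seen; the tests of injection, single arrays, lens share and paralog signal were chosen after the results were seen. Probe sets with no gene named here were left out of the gene tests, and of these 53551 an adjusted p under 0.05 was reached by 190 for tbx5 against control, 6885 for pitx2ab against control and 9784 for tbx5 against pitx2ab morpholino, as a signal in data not reported on by name. Groups of 3 were not tested for single samples far from the others. The median absolute difference from the mean of the group's other arrays was 0.089 for pitx2ab replicate 2. It was 0.066 and 0.064 for pitx2ab replicates 1 and 3, 0.06 to 0.068 in controls and 0.076 to 0.091 in tbx5 arrays.

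Every split of the 6 arrays of a comparison into 3 and 3 was fitted, and 10 splits are too few for a share under 0.05. For tbx5 against control the real split gave 1044 genes and the highest other 0, so 1 of 10 reached the real count; for lists these were 11, 8 and 1. For pitx2ab against control they were 8807, 0 and 1 for genes and 9, 9 and 2 for lists. For tbx5 against pitx2ab morpholino they were 9189, 0 and 1 for genes and 6, 9 and 4 for lists. In both comparisons that include the pitx2ab arrays, the number of called lists thus did not set the real split apart. Each mixed split has 2 arrays of 1 group on a side, so it keeps part of the real difference. Its list count is therefore no reference for unchanged groups and decides nothing.

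The rise of p53 and stress genes in pitx2ab morpholino embryos was weighed against injection, since p53 activation is a known off-target effect of morpholinos and the controls were uninjected. An equal response to any injected morpholino predicts a like rise in tbx5 morpholino embryos. There the 17 risen p53 genes had a median log2 change of 0.032 (0.782 under pitx2ab) and the 26 risen stress genes one of 0.176 (0.746 under pitx2ab), although 7 of these stress genes also rose. These genes were chosen by their rise under pitx2ab, but over all members the medians were -0.022 against 0.391 for p53 and 0.073 against 0.515 for stress genes, and without any 1 pitx2ab array at least 15 of the 17 p53 genes still rose. An equal response, and for p53 a single pitx2ab array, are thus unlikely as the whole of it, but a smaller injection response in the stress genes, a response that depends on dose or oligonucleotide sequence, a delay in development and an effect of losing Pitx2 could each remain, as the labels give no dose and the series holds no group injected with a control morpholino.

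The fall of lens genes in tbx5 morpholino embryos was weighed against a single array and a smaller share of lens tissue. Without any 1 tbx5 array at least 12 of the 18 genes still fell, with 12 left without replicate 3, and without control replicate 1 the lens list had 11 lower genes. A smaller share of lens would lower all bright lens genes alike. The 4 gamma M2 crystallin genes minus 22 other bright lens genes stood at -0.29 ± 0.09 in controls and 0.33 ± 0.35 in tbx5 morpholino embryos (SD, n = 3), a change of 0.621. These 4 genes were picked because they had not fallen, and tbx5 replicate 1 (-0.068) lay near control replicate 2 (-0.208), so this contrast excludes nothing; a single tbx5 array is unlikely as the whole of it, while a smaller lens, a delay of lens maturation and an effect on lens genes could each remain.

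The rise of tbx5a in tbx5 morpholino embryos was weighed against signal from its paralog on the same probes. Such signal predicts a rise of tbx5b, and tbx5b changed by -0.451. Cross-signal is thus unlikely, while a stabilised RNA bound by the morpholino, if tbx5a is its target, and a feedback on transcription could each give the rise, and these arrays cannot separate them.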

How the results depend on the processing

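The splits and all settings here were planned before the results were seen, and the tests chosen afterwards stand in the part above. The count of changed genes for tbx5 against control was 466 with each probe set tested on its own and 1685 with array weights. With only these groups in the fit it was 578. For pitx2ab against control that setting gave 9111 genes against 8807, so fewer arrays alone need not lower the count. The median SD of a gene was 0.087 in tbx5 arrays, 0.067 in controls and 0.073 in pitx2ab arrays. The causes were not tested. For pitx2ab against control and for tbx5 against pitx2ab morpholino the count was 15545 and 19218 with each probe set on its own, where more are tested. The genes shared between both control comparisons were 180 with each probe set on its own and 702 with array weights; the cause was not tested. With an estimated correlation camera called 0, 0 and 0 lists and the directional fry test 10, 19 and 26, against 11, 9 and 6 with the preset correlation. Leaving out 1 array gave 205 to 1542, 7572 to 9029 and 8147 to 8952 genes, 8 to 13, 9 to 10 and 6 to 7 lists, 103 to 630 shared genes and a correlation of 0.104 to 0.179; the cause was not tested. Single arrays left out gave -0.062 to 0.204 for crygm2b and -0.147 to 0.038 for crygm2c under the tbx5 morpholino, and -0.009 to 0.058 for tbx5a under the pitx2ab morpholino, none of which passed. Of the named genes that passed, 32 of 64 for tbx5 against control, 10 of 93 for pitx2ab against control and 3 of 50 for tbx5 against pitx2ab lost the threshold in some setting, none with a turned sign. With the replicate number as a block the counts were 1264, 9111 and 9481 genes, 11, 9 and 6 lists, 564 shared genes and a correlation of 0.137, the calls of ryr1b (tbx5 against control, adjusted p = 0.0555) and inaa (tbx5 against pitx2ab, 0.0607) ended and no other named gene's did, and 2 of 9 arrays correlated best with their own number in both other groups. Background signal was not in the files used, so what dim probe sets can show was not limited by a detection call.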

Other observations

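The gene groups in this part were chosen after the results were seen; the lists given with a camera adjusted p were not called in the planned fit. In pitx2ab morpholino embryos the list of BMP, Wnt and Hedgehog genes had 11 of 29 members higher and 6 lower (camera adjusted p = 0.519), and its members gli1 and hhip rose by 0.69 and 0.64. Its member id4 fell, at 10.13 to 10.24 against 11.19 to 11.46 in controls. The hypoxia and glycolysis list split, 10 of 33 higher and 9 lower (camera adjusted p = 0.955), with pfkfb3 at 1.29 and igfbp1a at 1.05 but ndrg1b at -1.45. Its median was -0.012 and its mean 0.033. The muscle transcript tnni2a.2 fell by 2.08, but the fast skeletal muscle list had 7 of 37 higher and 3 lower (median 0.016, camera adjusted p = 0.955). The mitochondrial creatine kinase gene ckmt2a fell by 1.91, and the myogenic factor gene myf5 rose by 1.01. The retinoic acid enzyme gene cyp26c1 rose by 1.18, the ciliary gene foxj1a by 1.11, the embryonic globin gene hbbe3 by 1.00 and the fin bud gene fgf10a by 0.47. The transcription factor genes prox1a (-1.15), tfap2b (-1.14) and otpb (-0.82) fell. The list epidermis and ionocytes had 14 of 36 higher and 3 lower (camera adjusted p = 0.0539) and passed without control replicate 2 (0.0337) or pitx2ab replicate 1 (0.0449), with averaged probe sets (0.0453) and after cyclic loess (0.0267), with anxa1c at 0.90 and krt18a.1 at 0.62.

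Some genes changed in opposite directions under the morpholinos against uninjected embryos. The apolipoprotein gene apom rose by 0.59 under the tbx5 morpholino and fell by 1.07 under the pitx2ab one, and differed by 1.66 between them. The pigment cell genes ednrba (0.52 and -0.61) and pnp4a (0.38 and -0.73) did the same. The kidney transporter genes slc12a3 (-0.59) and slc12a1 (-0.46, but -0.209 in its dimmer probe set) and pax8 (-0.55) fell under the tbx5 morpholino, 3 of 23 pronephros genes with 0 higher (camera adjusted p = 0.228), and these calls ended without control replicate 1 or 3, with adjusted p up to 0.0801, 0.0991 and 0.136, and that of pax8 with only these groups in the fit (0.0586). The gene slc12a3 was lower by a log2 change of -1.21 and slc12a1 by one of -1.13 in tbx5 than in pitx2ab morpholino embryos. Among lens genes, crybb1 was at -1.57 and crygm2c at 0.87 in tbx5 against pitx2ab morpholino embryos.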
